A study of Homo sapiens with 12 samples.

How the data were processed

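The series holds 12 ChIP-seq libraries from the colorectal cancer line DLD1 and its derivatives SA, SPH and METS, with 1 library of H3K4me3, H3K27me3 and H3K79me3 per line. Per the labels, the lines grew in McCoy's 5A medium with fetal bovine serum, and precipitation and library preparation used a Diagenode iDeal kit. The build was hg19 according to the submitters' processing notes. The aligner, the region caller, the counting program and any input control are not stated in the sources used here. Titles of the derivative libraries call them parental too, and the descriptions and characteristics were used to tell the lines apart.

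The deposited tables hold raw read counts per region, as judged from their values: whole numbers, with column totals that differ between lines and the same regions in the same order in the 4 lines of a mark. How the authors made the region sets is not stated. H3K4me3 has 36400 regions of 67 to 626 bp (median 433 bp) and H3K79me3 has 157878 regions of 36 to 582 bp (median 388 bp). H3K27me3 has 50000 intervals of 8 to 2304638 bp (median 2793 bp), of which 42.1% overlap an earlier interval and 7 repeat another. The H3K27me3 table was held only in part: its last line states that 7773 further entries were skipped, so its totals and CPM cover chromosomes 1 to 19 and this part of the table alone. Regions with 0 counts in every line numbered 771 for H3K4me3, 1625 for H3K27me3 and 1758 for H3K79me3.

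Counts were divided by the column total and scaled to CPM, the usual normalised read count for such tables. For counts of changed regions, 0.5 CPM was added to each value before the log2 ratio, and a region passed at 2-fold. Comparisons of a line with a pair of lines, or of pairs, required the threshold against every line of the other side. Folds of named regions used CPM without the added value, and pooled lines used the sum of their counts over the sum of their totals. Their 95% intervals are exact Clopper-Pearson intervals from SciPy, conditional on the sum of both counts. At 0 counts a bound was given against a floor of 3 counts, which leaves out the counting error of the other line, with the exact limit beside it. PCR copies were not marked, so intervals and floors cover counting error only. Counting error was also simulated in 20 draws, in which the summed count of each region over the 4 lines was dealt out by library total, and the highest total of these draws is given beside each count. In a test on simulated data, 197, 194 and 197 of 200 regions changed 4-fold were found for H3K4me3, H3K27me3 and H3K79me3. These were drawn from regions with a mean of 20 counts or more. In the same data 234, 30 and 3007 other regions also passed 2-fold.

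With 1 library per line, no p-value was computed for a line against DLD1. The mesenchymal and epithelial lines were compared by an edgeR quasi-likelihood model in which each line stood for 1 replicate, with library totals, all regions with a count, and a Benjamini-Hochberg threshold of 0.05. Its p-values cover only the spread between these 4 lines of 1 origin, and derivation, selection and culture are part of that spread. Both other partings of the 4 lines were fitted the same way. On simulated data with the fitted dispersion, the model found 62, 62 and 0 of 100 regions changed 2-fold and 99, 98 and 61 of 100 changed 4-fold for H3K4me3, H3K27me3 and H3K79me3, with 6, 7 and 1 false calls. For H3K79me3 this was repeated with 4 times the depth and with the dispersion of H3K27me3, chosen after the values were seen. No adjustment for a batch was made, as the labels name none.

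Before the data were examined, the following were fixed: the comparisons, the alternatives (TMM factors, quantile normalization, a smaller and a larger added value, a filter at the median, other fold thresholds, DESeq2 size factors and the DESeq2 Wald test, leaving out each line) and the rule for named regions. That rule took, per mark and derivative, at most 5 regions each way by log2 ratio to DLD1, among regions whose higher value of both lines reached the median of the pooled values, and for the mesenchymal parting 5 each way by the gap between the pairs of lines. The following were chosen after the values were seen: the near losses and gains, broad H3K27me3 intervals, H3K79me3 runs, the places where marks differed together, the model with TMM factors, the model on the other partings and the tests of explanations. For a list of regions, H3K27me3 or H3K79me3 nearby was tested against 10000 random lists matched on the H3K4me3 mean, unless fewer than 80% of its regions had a value. The exception is H3K79me3 beside the gains in METS, where the distinct H3K79me3 regions were compared with lists matched on their H3K79me3 mean of DLD1 and METS, and the result covers only the gains with a value. H3K79me3 counted as nearby within 5 kb.

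Runs were compared with 20 random placements of the same number of regions, within 10 classes of mean signal. Strong and weak regions were first split by the mean over the 4 lines. That split places a region high in a single line among the weak ones, so it was replaced by the mean over the sides compared, which treats a gain and a loss of equal size alike.

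The test of a mixture of cells in SA took its final form after earlier forms had been seen. These measured the spread of SA on the log2 scale, against simulated counts and then against matched lists, and were replaced because they did not allow for how counting error differs between regions. The final form divides by counting error and compares with lists drawn from 17646 unchanged regions.

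For joint differences, each H3K27me3 interval was represented by the H3K4me3 and H3K79me3 region inside it with the highest mean over the 4 lines. The 14 gene lists fixed beforehand, cell type markers included, were not used: the tables carry no gene names, and the gene table at hand is on another build than hg19. Software was R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.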

Results

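Chromatin carrying 3 histone H3 marks was immunoprecipitated and sequenced in 4 related human colorectal cancer cell lines, giving 12 libraries with 1 library per line and mark. H3K4me3 marks active promoters, H3K27me3 is the Polycomb mark of silenced chromatin, and H3K79me3 is laid down by DOT1L over the bodies of transcribed genes. DLD1 was the parental line and is described as epithelial. SA came from soft agar colonies and SPH from colonospheres, and both are described as mesenchymal. METS came from a lung metastasis in a xenograft and is described as epithelial. The series presents the 4 lines as a cell model of tumour progression, so each derivative was compared with DLD1, METS was compared with both mesenchymal lines, and the mesenchymal lines were compared with the epithelial lines.

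H3K4me3 had been counted at 36400 regions, with totals of 6722508 counts in DLD1, 7753937 in SA, 7153391 in SPH and 7303186 in METS. H3K27me3 was available at 50000 intervals on chromosomes 1 to 19, with 15605814, 18892326, 20410151 and 20286050 counts in the same order. H3K79me3 had been counted at 157878 regions, with 7521451, 7273964, 6165169 and 6432882 counts. There were no replicates, and values are counts scaled to the library total (CPM). Folds are ratios of CPM with exact 95% Clopper-Pearson intervals, which cover counting error only. Strong regions are those whose mean over the sides compared reached the median of that mean. Positions are on build hg19. No gene annotation on that build was used, so regions are given by position.

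In SA, H3K4me3 was lower than in DLD1 at more regions than it was higher. The region chr18:47792487-47792920 had 28.3 CPM in DLD1 and 5.55 CPM in SA, 5.10-fold lower (3.64 to 7.27). The regions chr19:15311350-15311819 and chr22:50919989-50920413 were 4.78-fold (3.14 to 7.5) and 4.36-fold (3.07 to 6.31) lower. The clearest gain was chr12:53443886-53444313, with 7.74 CPM in DLD1 and 27.9 CPM in SA, 3.60-fold higher (2.65 to 4.97). It was followed by chr11:2467324-2467632, 2.66-fold higher (1.97 to 3.64). At a threshold of 2-fold with 0.5 CPM added to each value, 192 regions were higher and 765 were lower, where counting error alone gave at most 254 in all. After quantile normalization the share higher went from 20.1 to 39.98% of the regions past the threshold. Of the regions past it with library totals, 2 of the higher and 18 of the lower were strong regions. In every comparison and mark, counts of this kind moved by more than 1.5 times with a smaller or a larger added value.

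SPH differed more from DLD1, and in this line some H3K4me3 regions were close to absent. The region chr19:58458529-58458946 had 208 counts in DLD1 and 1 in SPH, 221-fold lower (39.3 to 8784). The region chr5:178323009-178323430 was 83.7-fold lower (28.3 to 409), chr19:12475982-12476440 was 83.4-fold lower (28.2 to 407), and chr4:331708-332143 was 60.7-fold lower (23.4 to 225). Gains were smaller: chr17:79368491-79368909 was 4.02-fold higher (2.72 to 6.11), chr17:46276329-46276779 was 3.65-fold higher (2.47 to 5.52) and chr9:78506737-78507126 was 3.60-fold higher (2.69 to 4.88). The gain at chr12:53443886-53444313 seen in SA was also present in SPH, at 3.18-fold (2.32 to 4.42). In all, 1303 regions were at least 2-fold higher and 1215 lower, against at most 296 from counting error alone. Which side was larger depended on the scaling: 51.7% of these regions were higher with library totals, 48.2% with TMM factors and 39.2% after quantile normalization.

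A set of near losses was defined after the values were seen, as regions with at least 10 CPM in DLD1 and under 10% of that value in the derivative. SPH had 47 such regions, SA had 1 and METS had 0, and counting error alone gave 0 in each of 20 draws. At the 47 regions DLD1 had a median of 15.2 CPM. SPH kept a median of 2.57% of the DLD1 value. SA kept a median of 40.6% (interquartile range 31.1 to 48.2%) and lay below DLD1 at all 47. METS kept a median of 88.3% (71.3 to 120%) and lay below DLD1 at 28. Of the 38 of these regions inside a counted H3K27me3 interval, 3 lay in intervals at least 2-fold higher in SPH than in DLD1 and 0 in intervals 2-fold lower. In 10000 lists of regions matched on H3K4me3 a mean of 0.149 lay in such higher intervals, and 0.02% of the lists had as many as 3. The median log2 ratio of H3K27me3 in SPH to DLD1 over the 38 was -0.15, at percentile 59.6 of these lists. In SA the median was -0.05, at percentile 99.9, and in METS it was 0.01, at percentile 94.9. A high percentile was thus also seen in METS, which kept most of this H3K4me3, and these ratios share the DLD1 library. H3K79me3 had been counted within 5 kb of 8 of the 47 regions, too few to test, and was at least 2-fold lower in SPH at 5 of these and higher at 1.

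**Figure D1:**
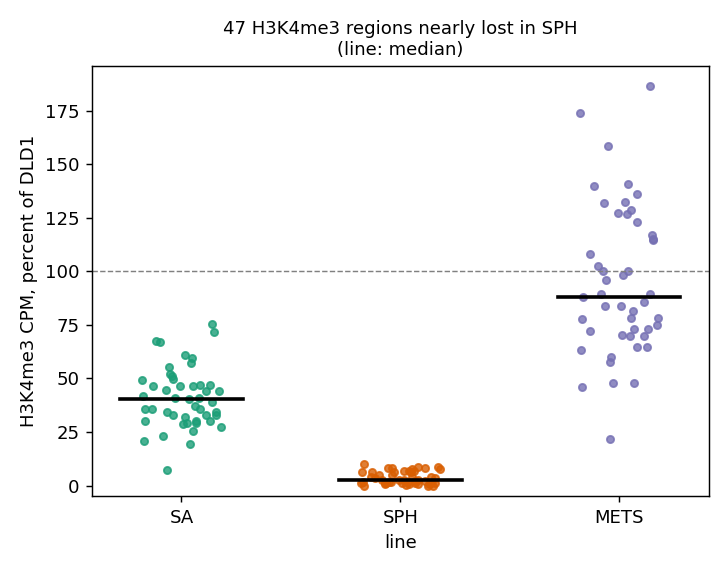
H3K4me3 at the 47 regions nearly lost in SPH, as percent of the DLD1 value in CPM (vertical axis), for SA, SPH and METS. Each point is 1 region, black bars are medians (40.6, 2.57 and 88.3%), the dashed line is the DLD1 level, and the regions were chosen for their low value in SPH.

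METS instead had H3K4me3 at a few places where DLD1 had almost none. The region chr11:2017963-2018424 had 3 counts in DLD1, 1 in SA, 3 in SPH and 311 in METS, 95.4-fold higher than DLD1 (32.4 to 465), and the adjoining chr11:2018490-2018997 was 23.8-fold higher (13.1 to 48.1). Further gains lay at chr17:2878865-2879378, 45.7-fold (15.3 to 224), at chr8:145019978-145020506, 44.5-fold (14.9 to 218), and at chr2:235403865-235404242, 7.54-fold (4.78 to 12.5). METS was lowest against DLD1 at chrX:75393001-75393441, 9.16-fold lower (5.25 to 17.3), and at chr5:76476106-76476724, 5.70-fold lower (4.24 to 7.8). By the mirrored definition, at least 10 CPM in METS and under 10% of that in DLD1, 14 regions were gained in METS and 0 in SA or SPH. These 14 had a median of 13.2 CPM in METS and 0.446 CPM in DLD1, and 12 of them were not strong regions. H3K79me3 had been counted within 5 kb of 9 of the 14, in 7 distinct regions, of which 5 were at least 2-fold higher in METS than in DLD1 and 0 lower. In 10000 lists matched on H3K79me3 a mean of 1.07 were higher, and 0.06% of the lists had as many.

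Across the genome 1425 H3K4me3 regions were at least 2-fold higher in METS than in DLD1 and 396 were lower, against at most 277 from counting error alone. Among strong regions 22 were higher and 25 lower, and among the weaker ones 1403 and 371. Against both mesenchymal lines at once, METS was at least 2-fold higher at 1218 regions and lower at 115, with 25 and 7 of these among strong regions. The balance depended on the scaling: after quantile normalization the share higher went from 78.3 to 56.9% against DLD1, and from 91.4 to 65.8% against the mesenchymal lines.

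**Figure D2:**
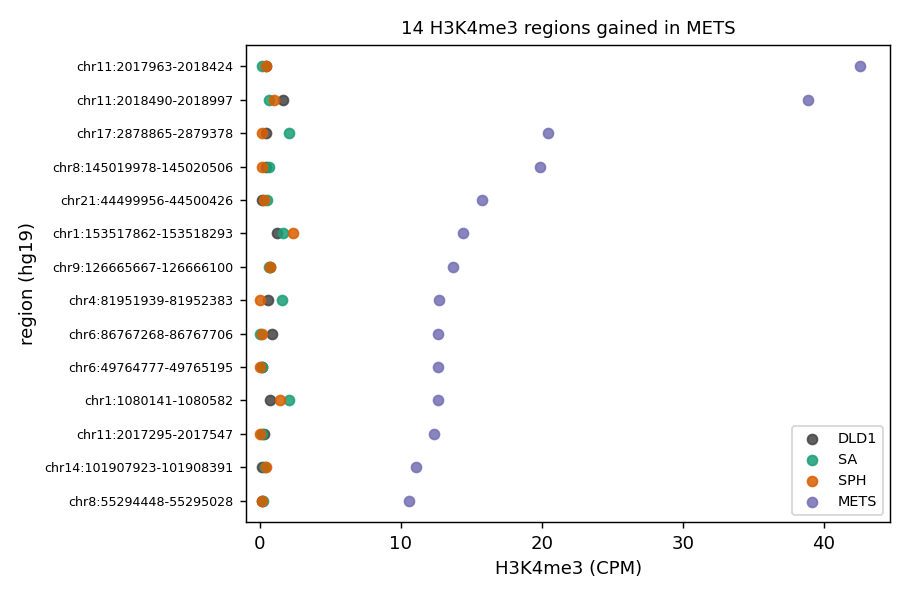
H3K4me3 in CPM (horizontal axis) at the 14 regions gained in METS (vertical axis, hg19 positions), with 1 point per line. METS lies between 10.5 and 42.6 CPM at these regions, and DLD1 lies at or below 1.64 CPM.

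Where the mesenchymal lines parted from the epithelial lines, H3K4me3 was mostly lower in SA and SPH. At chr9:95821036-95821455 the 4 counts were 74 in DLD1, 106 in METS, 6 in SA and 1 in SPH, and the mesenchymal lines together were 27.3-fold lower (13 to 69.0). Pooled in the same way, chr11:14993446-14993895 was 30.8-fold lower (12.9 to 96.4) and chr9:124061909-124062331 was 14.6-fold lower (7.68 to 31.05). The main gain was again chr12:53443886-53444313, 3.02-fold higher in the pooled mesenchymal lines (2.46 to 3.74). Both mesenchymal lines lay at least 2-fold below both epithelial lines at 251 regions and above them at 5, where counting error gave at most 7. By the mean over the 4 lines, 246 of the 251 and 4 of the 5 lay below the median region. The 2 other ways to part the 4 lines into pairs gave 62 and 10 regions.

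An edgeR quasi-likelihood model with each line taken as 1 replicate called 104 of 35629 H3K4me3 regions lower and 2 higher in the mesenchymal lines. The p-values cover only the spread between these 4 lines of 1 origin. The region chr9:95821036-95821455 fell by 4.72 on the log2 scale (edgeR adjusted p = 0.00111) and chr12:53443886-53444313 rose by 1.60 (edgeR adjusted p = 0.0170), each in both mesenchymal lines. The 104 regions called lower had medians of 9.22 CPM in DLD1, 13.3 in METS, 2.64 in SA and 0.839 in SPH, and they included 10 of the 47 regions nearly lost in SPH. DLD1 lay at least 2-fold above both mesenchymal lines at 79 of the 104, whereas METS alone did so at 13, the gain at chr11:2017963-2018424 among them. The number of calls was 9 with DESeq2 size factors, 34 with the DESeq2 Wald test and 0 in edgeR when regions below the median were left out, with 2148 at an unadjusted p under 0.05. Leaving out DLD1 gave 582, SA 5335, SPH 58 and METS 109.

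For H3K27me3, SA had higher signal over a few broad intervals. The 219-kb interval chr11:103546722-103765999 had 62.5 CPM in DLD1 and 302 CPM in SA, 4.83-fold higher (4.51 to 5.17), and SPH shared this gain at 4.20-fold (3.92 to 4.50). The interval chr10:3529086-3545030 was 5.88-fold higher (4.83 to 7.21) in SA, with 7.37 CPM in DLD1, 8.23 in SPH and 7.0 in METS. The short interval chr4:6675178-6677774 was 7.79-fold higher in SA (3.58 to 20.1) and 9.18-fold higher in SPH (4.26 to 23.5). The lowest in SA included chr9:76188531-76194414, 3.60-fold lower (2.47 to 5.35), an interval that was also 5.25-fold lower in METS (3.44 to 8.24). In all, 159 intervals were at least 2-fold higher and 236 lower, against at most 50 from counting error alone. The balance turned with the scaling, from 40.3% higher with library totals to 68.8% with TMM factors and 67.7% after quantile normalization.

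SPH had the largest single H3K27me3 loss named. The interval chr17:79369275-79375658 had 504 counts in DLD1, 251 in SA, 26 in SPH and 75 in METS, 25.4-fold lower in SPH (17.1 to 39.2) and 8.74-fold lower in METS (6.84 to 11.3). The intervals chr19:7981030-7983982 and chr19:917287-921015 were 8.0-fold (5.26 to 12.6) and 4.85-fold (3.67 to 6.48) lower in SPH. Gains in SPH lay at chr18:19746859-19748929, 8.41-fold (4.26 to 18.9), at chr17:14277456-14324343, 4.94-fold (4.48 to 5.45), and at chr13:94470677-94488397, 4.92-fold (3.95 to 6.18). Counts past 2-fold were 342 higher and 696 lower, against at most 55 from counting error alone. The share that was higher went from 32.9% with library totals to 51.2% with TMM factors and 54.5% after quantile normalization. Library totals also placed the median interval at a log2 ratio of -0.10 in SA and -0.07 in SPH, which TMM factors moved to -0.01 and 0.00.

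In METS, H3K27me3 was higher at chr12:10323141-10344400, 5.76-fold (3.99 to 8.55), and at chr19:29493462-29504862, 3.83-fold (3.06 to 4.84). It was lower at chr8:60031599-60033905, 8.77-fold (4.76 to 17.7), at chr1:2460184-2461684, 5.98-fold (4.13 to 8.88), and at chr5:52083774-52099880, 4.68-fold (3.69 to 6.0). This last interval had 14.4 CPM in SA, 13.9 in SPH and 4.34 in METS. Overall 244 intervals were at least 2-fold higher than in DLD1 and 369 lower, against at most 53 from counting error. METS lay at least 2-fold above both mesenchymal lines at 64 intervals and below both at 130, against at most 2. The share higher in that comparison was 33.0% with library totals, 20.1% with TMM factors and 20.6% after quantile normalization. At a threshold of 1.5-fold the larger side turned, with more intervals higher than lower.

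Broad intervals, taken after the values were seen as those of at least 50 kb with 300 counts or more in a line, showed differences over whole domains. Of 6309 such intervals, 18 were at least 2-fold higher and 31 lower in SA, 68 and 90 in SPH, and 37 and 70 in METS. These counts used library totals, with which the median broad interval lay at a log2 ratio of -0.18 in SA, -0.06 in SPH and 0.001 in METS. Some broad intervals lie inside others, so these are not counts of separate domains. In SPH alone, chr6:80816364-81055987 had 637 CPM per Mb against 182 in DLD1, 146 in SA and 181 in METS, 3.50-fold higher than DLD1 (3.22 to 3.81). In METS alone, chr14:85828801-85983278 had 1092 CPM per Mb against 355 in DLD1, 282 in SA and 305 in SPH, 3.07-fold higher (2.85 to 3.32). METS also had a 928-kb interval, chr13:66876967-67804468, at 2.91-fold the DLD1 level (2.79 to 3.02), and was 3.62-fold lower (3.36 to 3.89) over chr5:52083730-52255040.

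At 2-fold, the mesenchymal lines shared more H3K27me3 gains than losses. At chr4:6675178-6677774 they were together 11.4-fold above the epithelial lines (6.35 to 22.6), and at chr17:14277456-14324343 they were 3.91-fold above (3.67 to 4.17). Of the shared losses named by the rule, the interval with the most counts was chr4:86936276-87515284, 2.09-fold lower (2.03 to 2.15). Both mesenchymal lines lay at least 2-fold above both epithelial lines at 24 intervals and below them at 2, where counting error gave 0. The 2 other partings gave 8 and 0. The share higher was 92.3% at 2-fold but 48.6% of 282 intervals at 1.5-fold, and 48.6% of 671 with a smaller added value. The edgeR model called 166 of 48375 intervals higher and 142 lower, and 12 of the 166 lay on chromosome 13. On that chromosome the 1181-kb interval chr13:93879095-95059655 rose by 1.89 on the log2 scale (edgeR adjusted p = 8.02e-11) and chr13:92050929-93519490 rose by 1.65 (edgeR adjusted p = 1.10e-08), each in both mesenchymal lines. Other called intervals lie inside these, such as chr13:94470677-94488397, chr13:94806447-94840245 and chr13:93136859-93162347, so the 12 are not separate domains. With TMM factors the model called 250 higher and 68 lower, and with DESeq2 size factors 248 and 68. The DESeq2 Wald test called 86 higher and 15 lower, leaving out SA gave 1243 and leaving out SPH 200, and 0 were called by edgeR when intervals below the median were left out, with 2574 at an unadjusted p under 0.05.

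For H3K79me3, SA differed least from DLD1. The adjacent regions chr15:63335104-63335611 and chr15:63335616-63336032 were 5.32-fold (3.63 to 8.01) and 5.21-fold (3.59 to 7.74) lower in SA. Gains included chr1:40842647-40843062, 5.00-fold (2.65 to 10.2), and chr17:15857566-15857852, 4.53-fold (2.45 to 9.03). Over all regions 1699 were at least 2-fold higher and 3626 lower, against at most 2499 from counting error alone. The share higher went from 31.9% with library totals to 48.8% after quantile normalization.

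In SPH, H3K79me3 was higher over chromosome 17 around 79375267 and lower over chromosome 9 around 14306922. The region chr17:79375267-79375644 had 7.58 CPM in DLD1 and 63.9 CPM in SPH, 8.43-fold higher (6.38 to 11.3), and chr17:79387189-79387582 was 12.8-fold higher (6.21 to 30.6). On chromosome 9, chr9:14306922-14307422 had 81 counts in DLD1, 34 in SA, 2 in SPH and 21 in METS, 33.2-fold lower in SPH (8.90 to 279). The region chr9:14248011-14248348 had 0 counts in SPH, at least 11.2-fold lower against a floor of 3 counts and with an exact 95% limit of 8.71-fold. In all, 4788 regions were at least 2-fold higher and 8071 lower, against at most 3193 from counting error alone. The share that was higher went from 37.2% with library totals to 51.2% with TMM factors and 58.9% after quantile normalization. The median region lay at a log2 ratio of -0.12 with library totals and -0.02 with TMM factors.

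In METS, H3K79me3 appeared over sequence that had almost none in DLD1. The region chr11:2017254-2017610 had 0 counts in DLD1, 1 in SA, 1 in SPH and 111 in METS, at least 43.3-fold higher than DLD1 against a floor of 3 counts and with an exact 95% limit of 34.6-fold. The region chr11:2017925-2018332 was 61.2-fold higher (20.6 to 300). The region chrX:86796669-86797087 was 65.5-fold higher (17.7 to 547). Losses were smaller, 11-fold (6.82 to 18.9) at chr10:114141702-114142283, 13.4-fold (6.31 to 34.2) at chr11:34649417-34649674 and 10.7-fold (6.10 to 20.6) at chr17:56479687-56480021. Across all regions 11267 were at least 2-fold higher and 3251 lower, against at most 3022 from counting error alone, and among strong regions the split was 2923 higher and 2417 lower. After quantile normalization the share higher went from 77.6 to 55.3%. Against both mesenchymal lines METS was at least 2-fold higher at 5051 regions and lower at 1107; the share higher was 82.0% with library totals, 64.2% with TMM factors and 41.5% after quantile normalization.

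Part of the H3K79me3 regions past 2-fold lay in runs. Runs were defined after the values were seen, as 5 or more regions past 2-fold in one direction and at most 50 kb apart, among regions whose higher value of both lines reached the median. SA had 8 runs of higher and 26 of lower regions, SPH 146 and 143, and METS 202 and 139. Dealing the same regions at random among regions of like signal gave at most 1 and 3 runs in SA, 55 and 60 in SPH, and 115 and 42 in METS. This dealing ignores that neighbouring regions may belong to 1 stretch of signal. The excess shows that regions past 2-fold lay close together, not that they were separate differences. Runs held 14.9 and 17.9% of these regions in SA, 46.6 and 38.4% in SPH, and 46.5 and 59.6% in METS. In SPH the higher run with the most such regions, chr17:79226776-79399777, held 61 such regions of 77 and had 3.66-fold the DLD1 signal (3.52 to 3.8), and the lower run with the most, chr3:185432360-185540627, held 63 of 110 and was 2.58-fold lower (2.43 to 2.73). In METS, chrX:86752853-86913737 held 76 of 127 regions and was 17.2-fold higher than DLD1 (15.2 to 19.4), with 38.3 CPM in DLD1, 89.2 in SA, 13 in SPH and 658 in METS. The lower run in METS with the most such regions, chr10:114713722-114887456, held 110 of 182 regions and was 2.17-fold lower (2.12 to 2.22).

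For H3K79me3 the mesenchymal parting was smaller than the parting of SPH and METS from DLD1 and SA. The region chr6:129531717-129532145 had 28 counts in DLD1, 62 in METS, 3 in SA and 2 in SPH, 17.3-fold lower in the pooled mesenchymal lines (7.16 to 54.7), and chr7:16958317-16958636 was 32.3-fold lower (8.59 to 272). Both mesenchymal lines were at least 2-fold below both epithelial lines at 340 regions and above them at 9, against at most 38 from counting error, and after quantile normalization the total of 349 went to 140 and the share higher from 2.58 to 34.3%. The parting of SPH and METS from DLD1 and SA was larger, with 1247 regions higher and 121 lower. The edgeR model called 0 of 156120 regions between mesenchymal and epithelial lines, with 4675 at an unadjusted p under 0.05, and the DESeq2 Wald test called 0, with 1005. In simulation the edgeR model found 0 of 100 changes of 2-fold and 61 of 100 of 4-fold for this mark. The 0 calls thus do not show that such differences were absent. Leaving out DLD1 gave 345 calls, SA 206, SPH 76 and METS 0, whereas the parting of SPH and METS gave 2840 regions called higher and 515 called lower in these lines. The SPH and METS libraries also stood apart at the regions with the most counts in the H3K79me3 libraries, where each of the 5 highest was lower in both. Among them chr1:121485031-121485448 had 1377 CPM in DLD1, 1460 in SA, 872 in SPH and 857 in METS. The overlapping H3K4me3 region chr1:121484997-121485418 went the other way, with 704, 648, 1131 and 958 CPM. Whether counts at such places reflect the mark was not tested. Regions on the mitochondrial genome summed to 264, 446, 178 and 191 CPM in the H3K79me3 libraries, in the same order.

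**Figure D3:**
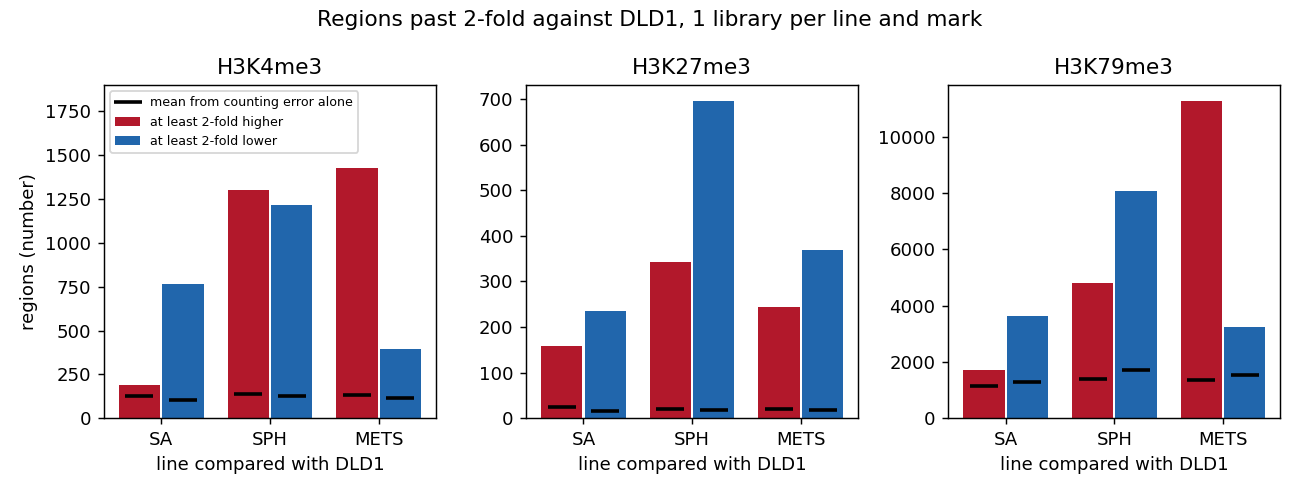
Number of regions (vertical axis) at least 2-fold higher or lower than in DLD1 in SA, SPH and METS, for each mark, with 0.5 CPM added to each value. Black bars are the mean from counting error alone, and the METS bars for H3K79me3 stand for 11267 higher and 3251 lower regions.

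Marks differed together at several places but not at every place looked at, all chosen after their values were seen. On chromosome 17, the H3K27me3 interval 79369275-79375658 that was 25.4-fold lower in SPH held some H3K4me3 regions that were higher in each derivative, such as 79369690-79370111 with 13.1 CPM in DLD1, 29.8 in SA, 36.5 in SPH and 30.9 in METS, and others that were not, such as 79373464-79373913 with 21.9, 24.8, 23.2 and 21.4 CPM. Summed over the 16 H3K4me3 regions from 79353110 to 79393986, this mark was 1.29-fold higher in SA (1.21 to 1.38), 1.38-fold in SPH (1.29 to 1.48) and 1.36-fold in METS (1.27 to 1.45). Summed over 41 regions from 79361454 to 79399777, H3K79me3 was 5.11-fold higher in SPH (4.83 to 5.41), 3.11-fold in METS (2.93 to 3.30) and 2.0-fold in SA (1.88 to 2.13). On chromosome 9, the interval 14081842-14398982 had 153 CPM of H3K27me3 in DLD1, 169 in SA, 318 in SPH and 190 in METS. H3K79me3, summed over 22 regions from 14224408 to 14313420, was 8.52-fold lower in SPH (6.94 to 10.6), 3.12-fold in METS (2.73 to 3.56) and 1.76-fold in SA (1.59 to 1.95). H3K4me3, summed over 9 regions, was 1.98-fold lower in SPH (1.81 to 2.17), 1.30-fold in METS (1.21 to 1.41) and 1.24-fold in SA (1.14 to 1.33). These H3K4me3 regions differed: 14312926-14313372 had 26.0 CPM in DLD1 and 3.22 in SPH, and 14322202-14322586 had 26.6 and 26.3. On chromosome 11, H3K4me3 and H3K79me3 were gained together in METS between 2017254 and 2018997, while the next H3K4me3 region, 2019459-2019780, had 13.2 CPM in DLD1 and 3.15 in METS.

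**Figure D4:**
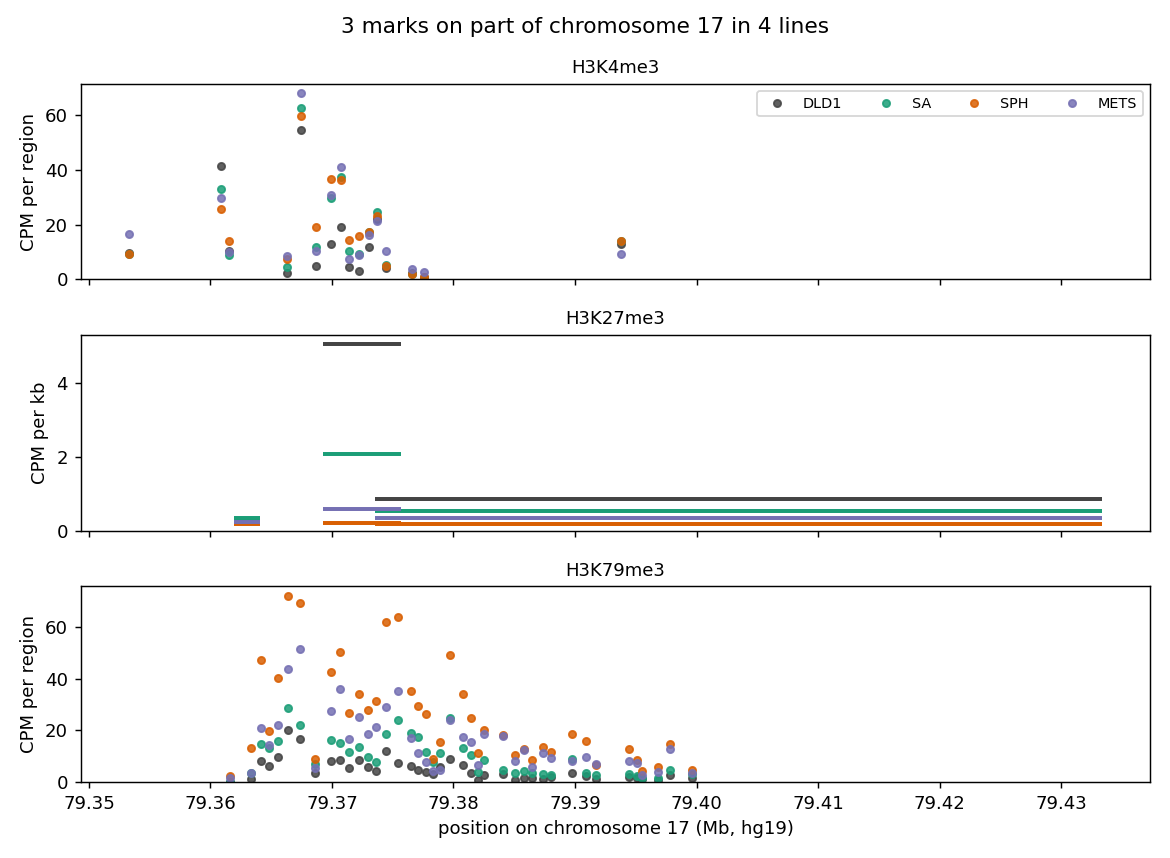
H3K4me3, H3K27me3 and H3K79me3 along part of chromosome 17 (horizontal axis, Mb on hg19) in the 4 lines, in CPM per region or, for H3K27me3, CPM per kb over each interval. SPH has 1.27 CPM of H3K27me3 in total over the interval where DLD1 has 32.3, and its H3K79me3 points lie above those of DLD1.

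Joint differences were counted over all H3K27me3 intervals that held a region of the other marks concerned, each mark represented by its region with the highest mean, and some were more frequent than independent lists would give. In SPH, H3K4me3 and H3K79me3 were both at least 2-fold lower in 19 intervals, against 2.51 from independent lists, and in METS both were higher in 17, against 6.08. Lower H3K4me3 with higher H3K27me3 occurred in 7 intervals in SPH, against 1.34, but lower H3K4me3 with lower H3K27me3 occurred in 19, against 7.5. In METS, higher H3K4me3 occurred with lower H3K27me3 in 6 intervals, against 2.02, and with higher H3K27me3 in 4, against 0.423. Over the 3 derivatives, differences of H3K4me3 and H3K27me3 in opposite directions summed to 20, against 6.57 from independent lists, and those in the same direction to 26, against 10.2. Intervals overlap, so these counts are not independent.

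The lowest Spearman correlation across regions between any pair of lines was 0.961 for H3K4me3 (SPH with METS), 0.972 for H3K27me3 (DLD1 with SPH) and 0.873 for H3K79me3 (SA with METS). With regions below the median left out, the lowest values were 0.883, 0.971 and 0.740. These correlations rest on differences in level between regions, and for H3K27me3 also on the widths of its intervals, so high values do not show that the lines were alike. Regions are not independent replicates.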

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

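Every test of an explanation in this part was chosen after the result was seen, and so were the definition of the near losses in SPH and the parting of SPH and METS from the other lines.

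Against DLD1, some regions lay past 2-fold in opposite directions in SPH and METS, and these differences between derivatives were not tested. H3K4me3 was lower in SPH and higher in METS at 72 regions, of which chr16:67233029-67233495 had 112 counts in DLD1, 110 in SA, 41 in SPH and 294 in METS. It was higher in SPH and lower in METS at 4 regions, such as chr6:143140840-143141266 with 33, 45, 80 and 14 counts. H3K27me3 was lower in SPH and higher in METS at 0 intervals and the reverse at 6, such as chr13:92050929-93519490 with 10359 counts in DLD1, 25218 in SA, 34521 in SPH and 6080 in METS. H3K79me3 was lower in SPH and higher in METS at 147 regions, such as chr11:2018372-2018924 with 8, 3, 0 and 189 counts, and the reverse at 9, such as chr6:130007252-130007789 with 204, 249, 359 and 82 counts. Counting error alone gave at most 2 regions in any of these groups.

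SA lay between DLD1 and SPH at the 47 H3K4me3 regions nearly lost in SPH, with a median of 40.6% of the DLD1 value. A choice of regions with high DLD1 values would have lowered METS as much, but METS kept a median of 88.3%, so this choice is not the whole cause. A single proportion of SPH-like cells in the SA culture, 61.7% at best, left an SD of 1.94 counting errors over the 47 regions (bootstrap 1.56 to 2.24; 1.87 without the farthest region), above the highest of 10000 lists of unchanged regions at 1.83. That argues against 1 uniform mixture, although 13 of the 47 regions had a larger counting error than any unchanged region. A partial loss in SA of regions nearly lost in SPH, both mesenchymal, may be a biological reading, as a hypothesis. Technical causes such as a mixture with 1 or more kinds of cell stay open.

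A higher background in the METS libraries would raise weak regions and leave strong ones balanced, and could so give the excess of higher over lower regions for H3K4me3 and H3K79me3. Among regions whose mean of DLD1 and METS reached the median, 46.8% of the H3K4me3 regions past 2-fold were higher, against 79.1% among the weaker regions, and for H3K79me3 the shares were 54.7% and 90.9%. Background and true gains at weak regions would both give these shares against DLD1, so neither is settled and a biological gain stays open. The sum over the mitochondrial genome was higher in METS than in DLD1 for H3K4me3 (249 against 132 CPM). For H3K79me3 it was lower (191 against 264 CPM). This sum was not tested as a measure of background. Against SA and SPH the H3K79me3 shares were 45.6% and 96.1%, but 78.1% of the 32 strong H3K4me3 regions past 2-fold were higher (exact 95% interval 60.03 to 90.7%), against 91.7% of the weaker ones, which is not balanced but does not clear the bound of 65% set against background and leaves it open there. The 14 gains of H3K4me3 in METS were compared with the 5207 other regions with no more DLD1 signal. There METS had a median of 1.10 CPM, below the lowest exact 95% limit of the gains at 8.32 CPM. An even background would raise weak regions alike, so it is not the whole cause of these gains. The 99th percentile of 5.06 CPM also lay below this limit, but the choice of the gains by high METS values nearly ensured that. A background that differs between regions stays open.

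H3K79me3 parted SPH and METS from DLD1 and SA at 1368 regions, more than the 349 of the mesenchymal parting. After the median of each 1-Mb bin was set to 0, 745 regions lay past 2-fold, of which 399 were among the 1368. Counting error centred in the same way gave at most 42 in all. A trend shared by whole 1-Mb bins is thus not the whole cause. Centring leaves differences between regions within a bin, so an effect of GC content at that scale was not tested and stays open. Chromosome shares moved together in SPH over DLD1 and METS over SA, which have no library in common: Pearson r was 0.877 over 23 chromosomes (Spearman rho 0.712), and 0.747 without chromosomes 16 and 19. The highest H3K79me3 regions and the mitochondrial sum were also lower in both libraries. A library-wide difference shared by the SPH and METS libraries would give all of these. A biological difference shared by SPH and METS would give the chromosome shares too. The mitochondrial sum went the other way in the H3K4me3 libraries, with 132 CPM in DLD1, 162 in SA, 323 in SPH and 249 in METS. The chromosome 1 region with the most counts did so as well. The lower values at these places are thus not counted for a biological difference. No biological explanation was tested, since no group of the design joins these lines.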

How the results depend on the processing

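The model with TMM factors and the alternatives for near losses, broad intervals and runs were chosen after the data were seen. Counts below are totals past the threshold for SA, SPH, METS, METS against SA and SPH, and the mesenchymal parting, in this order; the cause of a move was not tested beyond what a setting itself does, as a lower threshold or a smaller added value passes more regions. With an added value 10 times smaller the counts were 2594, 4413, 3249, 2101 and 620 for H3K4me3, 7946, 7975, 7138, 2462 and 671 for H3K27me3, and 16060, 26286, 25354, 12826 and 2124 for H3K79me3. With 5 times larger they were 157, 793, 354, 371 and 62; 79, 320, 179, 72 and 13; and 123, 1578, 2395, 847 and 7. At 1.5-fold they were 4060, 8170, 5414, 3362 and 897, then 4244, 6148, 4393, 1492 and 282, then 28230, 45045, 46784, 23440 and 3241, and the joint change of marks was 309. At 4-fold they were 41, 327, 290, 268 and 17, then 3, 11, 7, 7 and 1, then 36, 310, 601, 300 and 1. With regions below the median left out they were 15, 214, 37, 30 and 6 for H3K4me3, 224 (SA) and 404 (METS) for H3K27me3, and 963, 4569, 5147, 1535 and 47 for H3K79me3. Quantile normalization moved the H3K79me3 mesenchymal parting to 140.

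The larger side turned in these cases, given as percent higher. H3K4me3 SPH went from 51.7 to 48.2 (TMM), 39.2 (quantile), 30.1 (larger added value), 38.8 (below the median left out) and 4.59 (4-fold), and H3K4me3 METS from 78.3 to 43.2 (below the median left out; the median is of the mean over the 4 lines, which tends to leave out regions high in 1 line). H3K27me3 SA went from 40.3 to 68.8 (TMM), 67.7 (quantile), 53.2 (larger added value) and 100 (4-fold). H3K27me3 SPH went from 32.9 to 51.2, 54.5 and 63.6 (TMM, quantile, 4-fold), METS against SA and SPH from 33.0 to 56.8 (1.5-fold), and the mesenchymal parting from 92.3 to 48.6 (both at 1.5-fold and with the smaller added value). H3K79me3 SPH went from 37.2 to 51.2, 58.9, 70.8 and 53.2 (TMM, quantile, larger added value, below the median left out), and METS against SA and SPH from 82.0 to 41.5 (quantile) and 34.3 (below the median left out). The cause was not tested.

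The lowest correlation between lines was 0.95, 0.988 and 0.888 with Pearson in place of Spearman, and 0.883 (H3K4me3) and 0.740 (H3K79me3) with regions below the median left out. The edgeR model called 106 H3K4me3 regions, and 15 with TMM factors, 9 with DESeq2 size factors, 34 by the DESeq2 Wald test and 0 with regions below the median left out (2148 at an unadjusted p under 0.05). For H3K27me3 it called 308, the Wald test 101, and edgeR 0 with intervals below the median left out (2574 unadjusted). Leaving out 1 line at a time gave 58 to 5335 calls for H3K4me3, 200 to 1243 for H3K27me3 and 0 to 345 for H3K79me3; the lone line of a side was then assumed to vary like the other pair. Near losses in SPH numbered 109 and 15 at minimums of 5 and 20 CPM and 90 at 20% in place of 10%, and gains in METS 38 and 3 at these minimums. Broad intervals of at least 100 kb past 2-fold numbered 97 in SPH and 66 in METS. Of the values under other alternatives, 63 counts or correlations and 55 shares stayed within the limits set, and 28 shares moved without turning, such as H3K4me3 METS to 56.9 and METS against SA and SPH to 65.8 after quantile normalization. Gene lists and overlaps of peak lists were not run, for lack of gene names and of peaks called per line. No paired analysis was possible because the labels give no replicate numbers. The median H3K79me3 region held 19 to 26 counts per library, and in the simulation of its mesenchymal parting 0 of 100 changes of 2-fold and 61 of 100 of 4-fold were found. With 4 times the depth 5 and 67 were found, and with the lower dispersion of H3K27me3 (0.0232 in place of 0.0676) 18 and 88, so in this simulation the spread between lines limited calls more than depth.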

Other observations

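The definitions of runs and broad intervals used here were chosen after the data were seen, and so was the choice of regions by height. Further H3K79me3 runs were found in METS and SPH. In METS the run chr17:70391562-70588799 held 98 regions past 2-fold of 202 and had 2.17-fold the DLD1 signal (2.10 to 2.23), and chr7:50772553-50860573 had 2.51-fold (2.35 to 2.70), with 159 CPM in DLD1, 51.4 in SPH and 399 in METS. Lower runs in METS lay at chr4:77507333-77670859, 2.5-fold lower (2.41 to 2.60), and chr7:27778010-27838336, 2.25-fold lower (2.16 to 2.34). In SPH, chr17:46278478-46337866 was 2.94-fold lower in H3K79me3 (2.71 to 3.20), while the H3K4me3 region beside it, chr17:46276329-46276779, had 33 counts in DLD1 and 128 in SPH. Over this run H3K79me3 had 340 CPM in DLD1, 215 in SA, 115 in SPH and 180 in METS.

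Broad H3K27me3 intervals differed between the derivatives. The interval chr17:13399006-13505244 was 2.72-fold higher in SA (2.55 to 2.91) and 3.69-fold higher in SPH (3.46 to 3.94) than in DLD1. The interval chr12:127399766-127544946 was 3.52-fold lower in SPH (3.27 to 3.8), with 1151 CPM per Mb in DLD1, 696 in SA and 1269 in METS. In METS chr4:160587655-160698936 was 3.30-fold lower (2.98 to 3.65), where SA had 938 and SPH 956 CPM per Mb against 772 in DLD1. The interval chr14:30045687-30661104 was 2.73-fold higher in METS (2.64 to 2.81).

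The highest counts lay at single places that were left in. The H3K4me3 region with the most counts, chr1:121484997-121485418, had 704 CPM in DLD1, 648 in SA, 1131 in SPH and 958 in METS. Regions on the mitochondrial genome summed to 132, 162, 323 and 249 CPM in the H3K4me3 libraries, in the same order. In H3K27me3 the interval chr15:56922379-57210769 alone took 3.74% of the counts in DLD1, 3.31% in SA, 2.78% in SPH and 2.35% in METS.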
